A study of Homo sapiens with 6 samples.

How the data were processed

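PolyA-selected RNA of SH-SY5Y cells was measured in 6 stranded libraries, 3 after silencing of DDX5 and DDX17 (siDDX5-17) and 3 after the control siRNA siGL2. Groups and replicate numbers were taken from the sample titles. A table of whole read counts per gene was deposited by the authors, with FasterDB gene identifiers and symbols per the file headers. The submitters' processing notes name cutadapt, TopHat2 2.0.13, SAMtools 0.1.19, DESeq2 and the build hg19. The counting tool, its strand setting and its treatment of overlapping genes are not given in the sources used here, and the libraries were stranded, per the labels' protocols. A comparison table was deposited by the authors as well, which holds per gene, per the file headers, a mean normalized signal, a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value; it was used only for the overlap with the calls made here. DESeq2 with its older shrinkage prior, rerun on the deposited counts, gave log2 fold changes with a median absolute difference from the deposited ones of 0.0058, against 0.023 without it, so the deposited folds may be shrunken toward 0.

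The count table held 19426 genes, 3425 of them listed at 0 in every library; since genes that are broadly expressed, such as CTSD, are among these, a 0 is reported only as listed at 0. Total counts ran from 29190797 to 35530624 per library, and TMM factors from 0.984 to 1.018. Replicates of a group differed by more than counting noise in every pair (chi-square per degree of freedom 13.8 to 48.7), so no pair looked like a library deposited in duplicate. This says nothing of whether the replicates were separate cultures. Symbols were used as the files give them. The annotation at hand, GENCODE release 29, uses another genome build than hg19, so no coordinates are given; it served for gene order, strand, transcript GC content and length, and 96.6% of the genes were matched to it by symbol or synonym.

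Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 13152 genes, scaled with TMM and tested with the two-sided quasi-likelihood F test of edgeR 4.0.16 (estimateDisp, glmQLFit, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The design had no term but the group. Standard errors are the log2 fold change divided by the square root of F. CPM values are scaled by the TMM factors and given as mean ± SD over 3 libraries. Folds of genes with 1 to 3 counts in a group were given as ratios of summed counts, scaled by depth, with 95% counting intervals.

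The procedure was tested on simulated counts for the comparison of siDDX5-17 with siGL2, with 200 changed genes among 13078: 57.1% of genes changed by 1.5-fold, 92.2% of those changed by 2-fold and 98.5% of those changed by 4-fold were recovered, and 17 of the 181 calls (9.39%) were false. Changes under 1.5-fold can therefore be missed at this depth and number of replicates.

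Gene lists, 25 with 784 entries, were written before the data were examined, as were the tests, the alternatives and the rule for named genes, except where the closing section says otherwise; 746 entries were found in the count table. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, two-sided, adjusted over the 24 lists with at least 3 tested genes; the list of microRNA host transcripts had 1 tested gene and was left out. Camera with an estimated correlation called 0 lists, 2 having an unadjusted p under 0.05, and fry called 3. The genes named are DDX5 and DDX17; among changed genes with a mean of at least 1 CPM and no overlap between the groups, the 8 largest rises and 8 largest falls and the 4 smallest p-values in each direction; in each list, up to 2 that rose and up to 2 that fell with the smallest p, or the 2 with the smallest p where none passed; and among tandem neighbours the 4 risen and 2 fallen genes with the smallest p. Neighbour genes were added beside the tandem genes. Some genes that the rule selects are not reported here.

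A downstream tandem gene is a tested gene whose next annotated gene on its 5-prime side lies on the same strand and has at least 10 times its mean CPM; control genes have such a neighbour on the opposite strand. The 2 sets were tested with camera and adjusted together.

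Replicate numbers are shared between the groups. The deviations of same-numbered libraries from their group means correlated across genes at 0.44, 0.61 and 0.57, and each library correlated best with its own number, so the numbers were taken to pair the samples, on this evidence from the counts, since the labels say nothing of shared days or cultures; genes are not independent replicates in these correlations. In a principal component analysis the first component (61.1% of the variance) separated the groups and the second (21.2%) separated replicate 3 from the others. The main fit, set before the data were examined, leaves this pairing out, and the replicate block was fitted as an alternative. The square root of the common dispersion was 0.127 in the main fit and 0.074 with the block. A gene or list that did not pass in the main fit can therefore pass with the block.

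Alternatives were RLE and upper-quartile factors, no filter and a filter of 1 CPM in 3 libraries, the replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, other set tests and other neighbour definitions. A GC correction, alone and with the block, and a neighbour definition restricted to counted genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9.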

Results

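SH-SY5Y is a human neuroblastoma cell line. Its cells had been transfected with 20 nM siRNA against the mRNAs of DDX5 and DDX17, a pair of closely related RNA helicases of the DEAD-box family, or with the same concentration of a control siRNA, siGL2, directed against luciferase. RNA was taken 48 h later, and stranded libraries of polyadenylated RNA were sequenced from 3 replicates per group, called siDDX5-17 and siGL2 here. The total count was 32756104, 33177382 and 29190797 reads in siDDX5-17 replicates 1 to 3 and 35530624, 34432067 and 32507647 in siGL2 replicates 1 to 3. The share of counts from mitochondrial genes lay between 4.71% and 5.67% in the 6 libraries. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The comparison asks which transcripts of this cell line change when both helicases are depleted together.

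Both silenced genes were lower in each of the 3 siDDX5-17 libraries than in any siGL2 library. DDX5 fell from 1539 ± 80.0 CPM (SD, n = 3, CPM being counts scaled by library size) in siGL2 cells to 446 ± 100.2 CPM (SD, n = 3), a log2 fold change of -1.79 ± 0.15 (SE, edgeR adjusted p = 0.000222). DDX17 fell from 276 ± 9.10 CPM to 98.9 ± 15.7 CPM (SD, n = 3 each), a log2 fold change of -1.48 ± 0.12 (SE, edgeR adjusted p = 0.000164). The depletion of DDX5 was weakest in siDDX5-17 replicate 2, at 557 CPM, against 420 and 362 CPM in replicates 1 and 3. DDX17 stood at 117 CPM in that library, against 88.5 and 91.3 CPM.

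**Figure D1:**
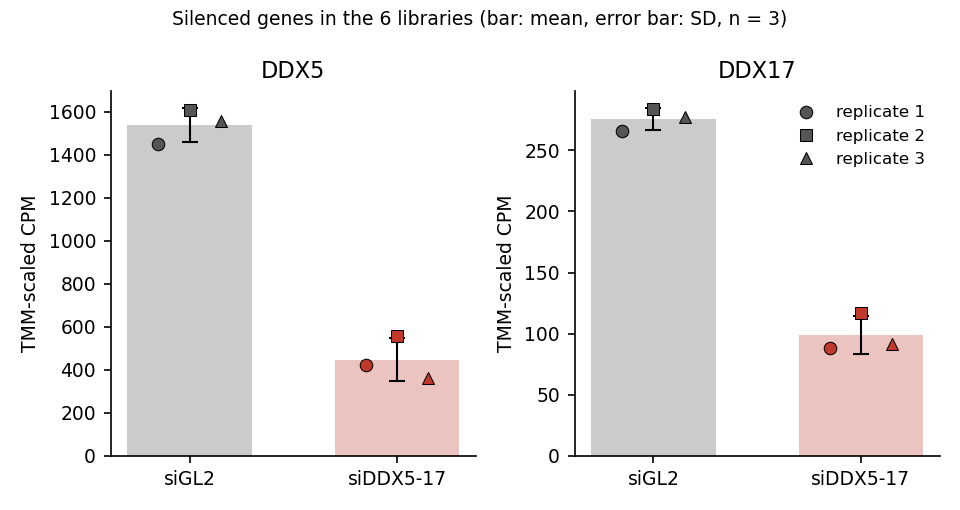
Abundance of DDX5 and DDX17 in CPM scaled by TMM factors (y axes, from 0) in the 6 libraries. Points are replicates, bars are group means and error bars are SD (n = 3); the siDDX5-17 libraries lie between 362 and 557 CPM for DDX5 and between 88.5 and 117 CPM for DDX17, below all siGL2 libraries.

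Silencing changed 2022 of the 13152 tested genes, with 841 higher and 1181 lower in siDDX5-17 cells (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The largest rises were in genes that were nearly silent in control cells. NPC1L1, a sterol transporter of the intestine, went from 0.124 ± 0.0978 to 15.5 ± 4.40 CPM (SD, n = 3 each), a log2 fold change of 6.90 ± 0.40 (SE, edgeR adjusted p = 9e-05). TMEM105, a predicted membrane protein, went from 0.313 ± 0.103 to 23.9 ± 11.8 CPM (SD, n = 3 each), a log2 fold change of 6.25 ± 0.44 (SE, edgeR adjusted p = 0.000138). LEFTY1, a secreted antagonist of nodal signalling, rose by 3.61 ± 0.20 on the log2 scale (SE, edgeR adjusted p = 9e-05) and IL16, a cytokine, by 4.18 ± 0.32 (SE, edgeR adjusted p = 0.000164).

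Among the other large rises were PDZD3, a PDZ-domain protein (5.03 ± 0.55), and the fucosyltransferases FUT3 (4.83 ± 0.50) and FUT5 (4.02 ± 0.28; log2 fold change and SE, edgeR adjusted p from 0.000138 to 0.000672). FUT3 and FUT5, like LEFTY1 and LEFTY2, are near-identical paralogs, so reads could have been assigned to either copy and their separate folds are uncertain. SIGLEC1, a macrophage lectin, had 3 counts in the siGL2 libraries together, all in replicate 1, and 212 in the siDDX5-17 libraries, a depth-scaled ratio of 77.0 with a 95% counting interval of 26.0 to 376. AP002380.2 had 2 and 292 counts, a ratio of 159 with a counting interval of 43.6 to 1320; these intervals cover counting error only. Both differed between the groups (edgeR adjusted p = 0.000726 and 0.000138). Without siGL2 replicate 1 the log2 fold change of NPC1L1 was 7.63, that of PDZD3 6.13 and that of FUT3 5.58, and SIGLEC1 had no control count left to set a fold against.

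The falls were smaller. INPPL1, the inositol phosphatase SHIP2, fell from 128 ± 12.3 to 44.4 ± 3.18 CPM (SD, n = 3 each), a log2 fold change of -1.52 ± 0.10 (SE, edgeR adjusted p = 0.000138). MTG1, a GTPase of the mitochondrial ribosome, changed by -1.51 ± 0.10, the neuronal vesicle protein NRSN2 by -1.43 ± 0.10 and the acylpeptide hydrolase APEH by -1.20 ± 0.09 (log2, SE, edgeR adjusted p from 0.000138 to 0.000164). The lipid droplet protein PLIN5 (-1.83 ± 0.21), AL589743.2 (-1.67 ± 0.17), RHPN1 (-1.65 ± 0.27), the histone mark reader ZCWPW1 (-1.64 ± 0.22), the D-2-hydroxyglutarate dehydrogenase D2HGDH (-1.62 ± 0.17) and the MAP kinase phosphatase DUSP2 (-1.61 ± 0.31) fell as well (log2, SE, edgeR adjusted p from 0.000563 to 0.00812). The nudix hydrolase NUDT18 had the lowest log2 fold change among the genes named here, -1.97 ± 0.35 (SE, edgeR adjusted p = 0.00584).

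The groups did not overlap in 2020 of the 2022 changed genes. Over all tested genes 35.8% showed no overlap, against 10% given by chance for 3 against 3. Of the changed genes, 330 rose and 148 fell by at least 2-fold, and 79 rose by at least 8-fold by the fitted fold, which is no bound for the genes without a siGL2 count, 2 of all tested. With the replicate block, that is the replicate number as a covariate, 4878 genes passed (2216 higher, 2662 lower), among them all 2022. Block counts given below for single lists are to be read against these 2216 and 2662 of all 13152 tested genes. The balance of directions depended on the settings: 41.6% of the changed genes were higher with TMM and 51.3% with upper-quartile factors (1028 higher, 977 lower). It was 45.4% with the replicate block alone, 49.6% with a correction for GC content alone and 52.7% with both together (3933 higher, 3528 lower). The count was 1301 without siDDX5-17 replicate 1, 972 without siGL2 replicate 1 and 1112 without siGL2 replicate 2. Without siDDX5-17 replicate 3 it was higher than with all 6 libraries, at 2251.

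**Figure D2:**
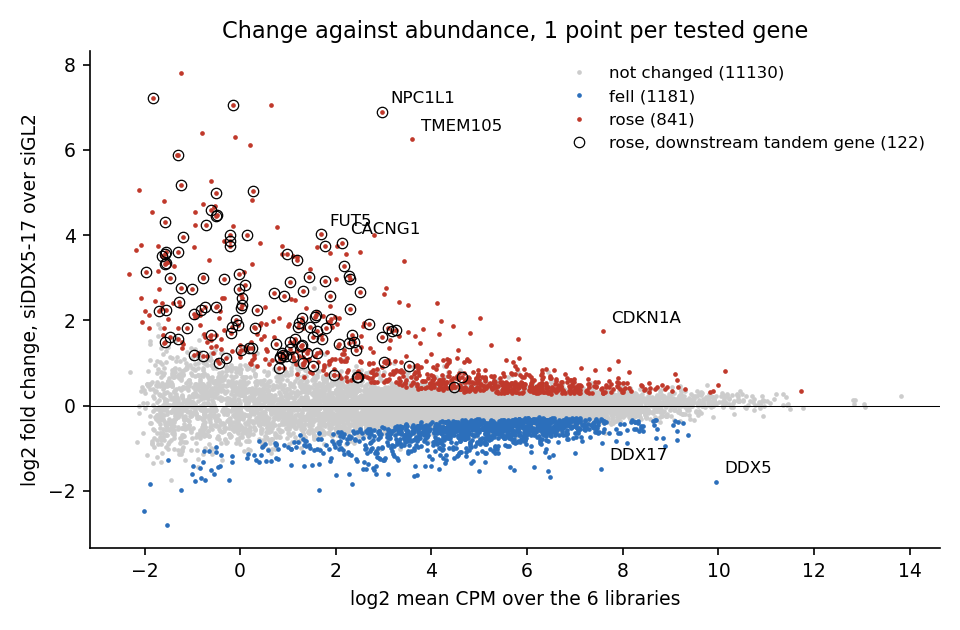
Log2 fold change of siDDX5-17 over siGL2 (y axis) against log2 mean CPM over the 6 libraries (x axis), 1 point per tested gene, with 841 genes that rose in red, 1181 that fell in blue and genes that did not pass in grey. Circles mark the 122 risen genes that lie downstream of a more abundant neighbour on the same strand, and the 2 tested genes without a siGL2 count stand at their fitted value.

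Of 31 tested genes known to be activated by p53, 15 rose and 1 fell, and 19 rose and 1 fell when adjusted over the list alone; the median log2 fold change was 0.36 (camera adjusted p = 1.7e-06), above 0 in all 3 same-numbered pairs. The list gave an adjusted p = 0.66 with an estimated correlation and 0.043 by fry, a test of whether its genes move on balance one way; 21 rose and 4 fell with the replicate block. CDKN1A, the cyclin-dependent kinase inhibitor p21, went from 88.0 ± 2.32 to 294 ± 90.7 CPM (SD, n = 3 each), a log2 fold change of 1.74 ± 0.19 (SE, edgeR adjusted p = 0.000669). GADD45A, a DNA damage response gene, rose by 1.10 ± 0.12 (log2, SE, edgeR adjusted p = 0.000723), whereas the DNA repair gene XPC changed by -0.56 ± 0.10 (log2, SE, edgeR adjusted p = 0.00529).

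Immediate-early genes, the fast transcriptional response to growth signals and stress, rose in 10 of 20 cases, and in 14 when adjusted over the list alone, with a median log2 fold change of 0.54 (15 rose and 1 fell with the replicate block; camera adjusted p = 1.7e-06) that was above 0 in all 3 same-numbered pairs. The list gave an adjusted p = 0.54 with an estimated correlation and 0.041 by fry. KLF6 rose by 0.66 ± 0.11 (log2, SE, edgeR adjusted p = 0.00481). IER5 rose by 0.50 ± 0.11 (edgeR adjusted p = 0.0122), a call that ended without siGL2 replicate 1 (adjusted p = 0.0513). Of 27 hypoxia and glycolysis genes 12 rose and 2 fell (18 and 2 when adjusted over the list alone), with a median of 0.36 (camera adjusted p = 1.7e-06), again above 0 in all 3 pairs, an adjusted p = 0.54 with an estimated correlation and 0.041 by fry. PDK1, the kinase that inhibits pyruvate dehydrogenase, rose by 1.02 ± 0.11 and the hypoxia-induced histone demethylase KDM3A by 0.62 ± 0.10 (log2, SE, edgeR adjusted p = 0.000549 and 0.00319). The phosphofructokinase PFKL (-0.60 ± 0.14) and the prolyl hydroxylase EGLN3 (-0.46 ± 0.14) fell (edgeR adjusted p = 0.0191 and 0.0463). The PFKL call ended without siDDX5-17 replicates 1 or 2 or siGL2 replicates 2 or 3 (adjusted p = 0.0587 to 0.0794), and the EGLN3 call without siDDX5-17 replicates 2 or 3 or siGL2 replicates 1 or 2 (adjusted p = 0.0836 to 0.182). Of the hypoxia and glycolysis genes 20 rose and 2 fell with the replicate block.

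Of 43 tested genes of DNA replication and the G1/S transition 9 fell, 13 when adjusted over the list alone, and 40 had a negative fold change, with a median of -0.37 (camera adjusted p = 1.7e-06) that was below 0 in all 3 same-numbered pairs. The list gave an adjusted p = 0.72 with an estimated correlation and 0.37 by fry; with the replicate block 33 of its genes fell. LIG1, the ligase that joins Okazaki fragments, changed by -0.87 ± 0.13 and POLA1, the catalytic subunit of DNA polymerase alpha, by -0.95 ± 0.17 (log2, SE, edgeR adjusted p = 0.00258 and 0.00569). Mitosis and G2/M genes had a median of -0.13, and the list did not pass (38 tested, 1 fell, 1 when adjusted over the list alone, camera adjusted p = 0.078); with the replicate block it passed (0.021) and 10 fell. The mitosis list gave an adjusted p = 0.72 with an estimated correlation, and 0.77 with the replicate block as well. Its pair medians were 0.07, -0.18 and -0.33. The 1 was the centromeric histone CENPA, at -0.46 ± 0.10 (log2, SE, edgeR adjusted p = 0.0131), which lost its call without siGL2 replicate 2 (0.0587). With the preset correlation the mitosis list passed without siDDX5-17 replicate 1 (0.00508), siDDX5-17 replicate 2 (0.00359), siGL2 replicate 1 (0.0133) or siGL2 replicate 3 (0.0089). Its adjusted p was 0.856 without siDDX5-17 replicate 3, and it gave an adjusted p = 0.72 with an estimated correlation over all 6 libraries.

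Of 26 tested replication-dependent histone genes, whose mRNAs normally lack a poly(A) tail, 5 rose, also when adjusted over the list alone, with a median of 0.34 (camera adjusted p = 0.027) and pair medians of 0.70, 0.02 and 0.26; the list gave an adjusted p = 0.72 with an estimated correlation. HIST1H2AC rose by 1.04 ± 0.23 and HIST1H1C by 0.72 ± 0.16 (log2, SE, edgeR adjusted p = 0.0166 and 0.0179). Genes of this list can be similar in sequence, so their separate counts may be uncertain, which was not checked here. The HIST1H2AC call ended without siGL2 replicate 1 (0.0618), and that of HIST1H1C without siDDX5-17 replicate 1 (0.0608), siGL2 replicate 2 (0.0683) or siGL2 replicate 3 (0.0627). The list lost its call without siDDX5-17 replicate 1 (0.291), siDDX5-17 replicate 3 (0.0713) or siGL2 replicate 2 (0.0597), with upper-quartile factors (0.0721), at 1 CPM in 3 libraries (0.0535) and with the GC correction (0.0718). In the fit with the replicate block 8 rose.

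**Figure D3:**
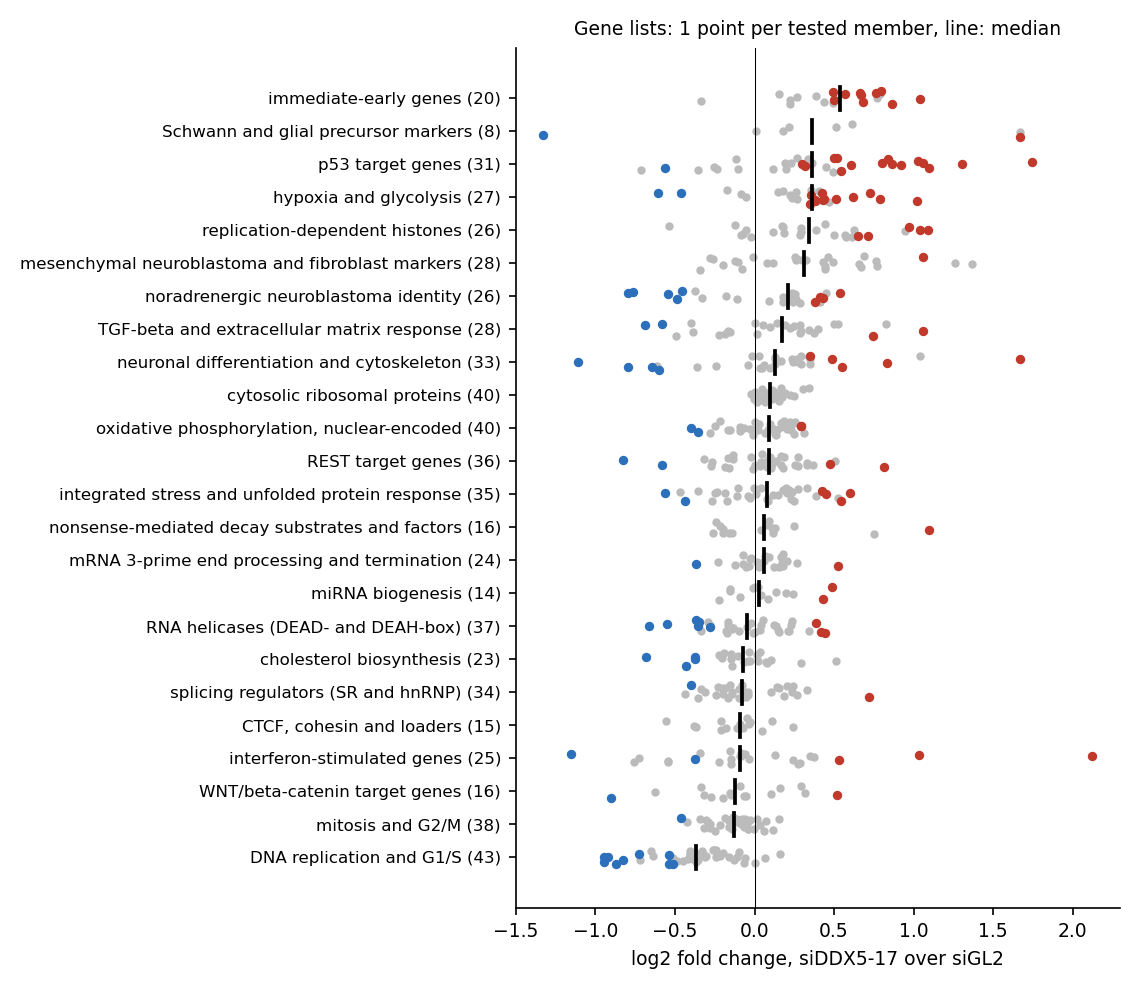
Log2 fold change of siDDX5-17 over siGL2 (x axis) for each tested member of the 24 tested gene lists (y axis, number tested in parentheses), with members past the threshold in red (rose) or blue (fell) and a black line at each median. The immediate-early median lies at 0.54 and that of DNA replication and G1/S at -0.37.

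Neuroblastoma identity genes moved in both directions. Of 26 noradrenergic genes, 4 rose and 5 fell (5 and 6 when adjusted over the list alone; median 0.21, camera adjusted p = 0.35). The receptor kinase RET went from 710 ± 83.1 to 409 ± 18.5 CPM (SD, n = 3 each), a log2 fold change of -0.80 ± 0.10 (SE, edgeR adjusted p = 0.00135), and DDC, the decarboxylase of catecholamine synthesis, changed by -0.76 ± 0.11 (edgeR adjusted p = 0.00214). ZNF536 rose by 0.41 ± 0.09 (edgeR adjusted p = 0.0143), a call that ended without siGL2 replicate 1 (0.0525) or siGL2 replicate 2 (0.0649). Of the noradrenergic genes 13 rose and 6 fell with the replicate block.

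Of 33 genes of neuronal differentiation and the cytoskeleton, 5 rose and 4 fell (6 and 4 when adjusted over the list alone; median 0.13, camera adjusted p = 0.12). The neurotrophin receptor NGFR rose by 1.67 ± 0.25 and the microtubule-binding protein DCX by 0.83 ± 0.15 (log2, SE, edgeR adjusted p = 0.00259 and 0.00607), while RET, also in this list, fell with the value above. With the replicate block 14 rose and 6 fell, and with the block and the GC correction together the list passed (0.0401). It gave an adjusted p = 0.72 with an estimated correlation and 0.67 with the replicate block as well. Targets of the neuronal repressor REST, 36 tested, gave 2 rises and 2 falls (1 and 1 when adjusted over the list alone; median 0.09, camera adjusted p = 0.30; 6 and 5 with the replicate block). The neuropeptide precursor VGF rose by 0.81 ± 0.14 (edgeR adjusted p = 0.00494) and DNM1 changed by -0.58 ± 0.12 (edgeR adjusted p = 0.0104; 0.0513 without siDDX5-17 replicate 1). RUNDC3A (0.48 ± 0.13, edgeR adjusted p = 0.0384) lost its call when any library but siDDX5-17 replicate 1 was left out (0.0594 to 0.145), and BDNF (-0.83 ± 0.25, edgeR adjusted p = 0.0485) when any of the 6 was (0.0505 to 0.164) and by DESeq2 (0.0885).

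Mesenchymal neuroblastoma and fibroblast markers, fixed as markers of another cell state, had a median of 0.31 over 28 genes (camera adjusted p = 0.027), above 0 in all 3 same-numbered pairs. The list gave an adjusted p = 0.72 with an estimated correlation, and 1 gene rose over all genes tested. Adjusted over the list alone, 0 passed in edgeR, against 8 higher and 1 lower at an unadjusted p under 0.05. Adjusted over all genes, 2 were higher by DESeq2 and 1 by limma-voom. With the replicate block 16 rose and 3 fell. The list lost its call without siDDX5-17 replicate 1 (0.156), siDDX5-17 replicate 3 (0.113) or siGL2 replicate 2 (0.152), with upper-quartile factors (0.0568), at 1 CPM in 3 libraries (0.122) and with the GC correction (0.0657).

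Of 8 Schwann and glial precursor markers, 1 rose (NGFR) and 1 fell (3 and 1 when adjusted over the list alone; median 0.36, camera adjusted p = 0.16; 4 rose with the replicate block). The 1 that fell was the neuregulin receptor ERBB3, at -1.33 ± 0.30 (edgeR adjusted p = 0.0166), a call that ended without siDDX5-17 replicates 1 or 2 or siGL2 replicates 1 or 2 (0.0513 to 0.0671). Of 28 genes of the TGF-beta and extracellular matrix response, 2 rose and 2 fell, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.30; 11 and 5 with the replicate block). Its laminin subunit LAMB1 changed by -0.69 ± 0.10 (edgeR adjusted p = 0.00205) and SMAD6, an inhibitor of BMP signalling, by 0.75 ± 0.16 (edgeR adjusted p = 0.013; 0.0543 without siGL2 replicate 1). The other gene that fell was the metalloprotease ADAM19 (-0.58 ± 0.15, edgeR adjusted p = 0.0252), a call that ended without siDDX5-17 replicate 2 or any siGL2 replicate (0.0512 to 0.102).

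Other RNA helicases of the DEAD- and DEAH-box families, 37 tested, gave 3 rises and 6 falls (4 and 7 when adjusted over the list alone; median -0.05, camera adjusted p = 0.44; 8 and 9 with the replicate block). The nucleolar helicases DDX54 and DDX50 changed by -0.67 ± 0.11 and -0.55 ± 0.09 (log2, SE, edgeR adjusted p = 0.00348 and 0.00529). EIF4A2 (0.44 ± 0.10) and DDX41 (0.39 ± 0.09) rose (edgeR adjusted p = 0.019 and 0.0199), calls that ended without siDDX5-17 replicate 1 (EIF4A2, 0.0566), siGL2 replicate 1 (0.0953 and 0.082), siGL2 replicate 2 (0.0739 and 0.0713) or siGL2 replicate 3 (DDX41, 0.0582). Of 14 genes of microRNA biogenesis 2 rose, also when adjusted over the list alone (median 0.03, camera adjusted p = 0.33; 3 and 1 lower with the replicate block), among them TNRC6B by 0.43 ± 0.11 (edgeR adjusted p = 0.0326). The TNRC6B call ended when any library but siDDX5-17 replicate 1 was left out (0.0511 to 0.136).

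Splicing regulators (34 tested, 1 rose, 1 fell, median -0.08, camera adjusted p = 0.40) and factors of mRNA 3-prime end processing and termination (24 tested, 1 and 1, also when adjusted over the list alone, median 0.06, camera adjusted p = 0.29) changed little as lists. Of the splicing regulators 6 rose and 10 fell with the replicate block, and of the 3-prime end factors 3 and 2. Adjusted over the list alone, edgeR called 0 splicing regulators, against 5 higher and 7 lower at an unadjusted p under 0.05. Adjusted over all genes, DESeq2 called 3 higher and 4 lower and limma-voom 1 lower. The splicing factors NOVA2 (0.72 ± 0.20, edgeR adjusted p = 0.041) and TRA2A (-0.40 ± 0.11, edgeR adjusted p = 0.0321) changed. The NOVA2 call ended when any library but siDDX5-17 replicate 1 was left out (0.0778 to 0.14), and that of TRA2A without siDDX5-17 replicate 1 or any siGL2 replicate (0.0571 to 0.113). The poly(A)-binding protein PABPN1 rose by 0.52 ± 0.12 (edgeR adjusted p = 0.0209; 0.0915 without siGL2 replicate 1 and 0.0658 without siGL2 replicate 2) and the cleavage factor CPSF4 changed by -0.36 ± 0.10 (edgeR adjusted p = 0.0331; 0.0772 to 0.143 without any library but siDDX5-17 replicate 3). CTCF, cohesin and its loaders (15 tested, median -0.09, camera adjusted p = 0.29) had 0 calls over all genes in edgeR, DESeq2 and limma-voom. In edgeR 0 also passed when adjusted over the list alone, against 1 lower at an unadjusted p under 0.05. With the replicate block 1 gene of this list rose and 4 fell. Its members with the smallest p were the cohesin subunit SMC1A, at -0.38 ± 0.14 (edgeR adjusted p = 0.107, 0.000224 with the replicate block), and the cohesin acetyltransferase ESCO2, at -0.55 ± 0.26 (0.178, 0.000454 with the replicate block, 0.0434 without siDDX5-17 replicate 2).

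Of 40 cytosolic ribosomal protein genes 38 had a positive fold change, with a median of 0.10 (camera adjusted p = 0.015, but adjusted p = 0.72 with an estimated correlation) that was above 0 in all 3 same-numbered pairs. In edgeR 0 passed, also when adjusted over the list alone, against 3 higher at an unadjusted p under 0.05. Adjusted over all genes, 1 was higher by DESeq2 and 0 by limma-voom. With the replicate block 7 rose. RPS9 stood at 0.34 ± 0.12 (edgeR adjusted p = 0.0815, 0.00089 with the replicate block) and RPS19 at 0.30 ± 0.12 (0.127, 0.0041 with the replicate block). The list lost its call without siDDX5-17 replicate 3 (0.494) or siGL2 replicate 2 (0.164). Nuclear-encoded genes of oxidative phosphorylation, 40 tested, gave 2 rises and 2 falls (median 0.09, camera adjusted p = 0.24; 9 and 5 with the replicate block). Adjusted over the list alone 0 passed in edgeR, against 7 higher and 5 lower at an unadjusted p under 0.05. Adjusted over all genes, DESeq2 called 4 higher and 2 lower and limma-voom 2 and 2. UQCRC2 (0.29 ± 0.08), COX5B (0.30 ± 0.09), UQCRC1 (-0.40 ± 0.10) and ATP5A1 (-0.36 ± 0.09) passed (edgeR adjusted p from 0.0207 to 0.0483). Each lost its call without siDDX5-17 replicate 2, siGL2 replicate 1 or siGL2 replicate 2 (0.0596 to 0.198). The UQCRC2, COX5B and UQCRC1 calls also ended without siDDX5-17 replicate 1, that of COX5B without siDDX5-17 replicate 3, and those of UQCRC2, COX5B and ATP5A1 without siGL2 replicate 3 (0.0535 to 0.108).

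Interferon-stimulated genes (25 tested, 3 rose, 2 fell, also when adjusted over the list alone; 4 and 5 with the replicate block) had a median of -0.09 and a mean of -0.01, while camera gave the opposite sign with an adjusted p = 0.99. The exonuclease ISG20 rose by 2.12 ± 0.20 and DDX58, the RNA sensor RIG-I, by 1.03 ± 0.13 (edgeR adjusted p = 0.000381 and 0.00133), while RSAD2 (-1.16 ± 0.32) and HERC5 (-0.37 ± 0.11) fell (edgeR adjusted p = 0.0374 and 0.0434). The RSAD2 call ended when any library but siGL2 replicate 3 was left out (0.0596 to 0.157) and the HERC5 call when any of the 6 was (0.0565 to 0.14). Genes of the integrated stress and unfolded protein response (35 tested, 4 rose, 2 fell, also when adjusted over the list alone; median 0.08, camera adjusted p = 0.16; 10 and 5 with the replicate block) passed as a list without siGL2 replicate 2 (0.015). That list gave an adjusted p = 0.72 with an estimated correlation over all 6 libraries. The chaperone CALR rose by 0.60 ± 0.11 (edgeR adjusted p = 0.00715) and DDIT4 by 0.54 ± 0.13 (edgeR adjusted p = 0.0192; 0.0676 without siGL2 replicate 1, 0.0752 without siGL2 replicate 2). EDEM1 (-0.44 ± 0.11) and PHGDH (-0.56 ± 0.16) fell (edgeR adjusted p = 0.027 and 0.047). The EDEM1 call ended without siDDX5-17 replicate 1 or any siGL2 replicate (0.0558 to 0.109), and that of PHGDH without siDDX5-17 replicates 1 or 3 or siGL2 replicates 1 or 2 (0.107 to 0.152).

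Of 23 genes of cholesterol biosynthesis 4 fell, also when adjusted over the list alone (median -0.07, camera adjusted p = 0.25; 2 rose and 6 fell with the replicate block), among them lanosterol synthase, LSS (-0.68 ± 0.11, edgeR adjusted p = 0.00339), and mevalonate kinase, MVK (-0.43 ± 0.10, edgeR adjusted p = 0.0181), whose call ended when any library but siDDX5-17 replicate 3 was left out (0.0524 to 0.0869). Of 16 WNT/beta-catenin target genes TNFRSF19 rose (0.52 ± 0.14) and NKD1 fell (-0.90 ± 0.24; edgeR adjusted p = 0.0352 and 0.0323), 1 and 1 also when adjusted over the list alone (median -0.12, camera adjusted p = 0.48; 3 and 3 with the replicate block). The TNFRSF19 call ended without siDDX5-17 replicate 1 or any siGL2 replicate (0.0655 to 0.125), and that of NKD1 without any of the 6 libraries (0.0564 to 0.118). Of 16 genes listed as substrates or factors of nonsense-mediated decay GADD45A rose (1.10 ± 0.12), also when adjusted over the list alone (median 0.06, camera adjusted p = 0.67; 2 rose and 2 fell with the replicate block).

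Genes lying downstream of a more abundant gene on the same strand, here called downstream tandem genes, included a larger share that rose than the control genes did. Of 549 such genes, whose nearest upstream neighbour had at least 10 times their mean CPM, 122 rose (22.2%) and 33 fell, with a median log2 fold change of 0.21 (camera adjusted p = 5.5e-05). The set gave an adjusted p = 0.42 with an estimated correlation; with the replicate block 185 rose and 90 fell. Of 294 control genes whose upstream neighbour was as much more abundant but lay on the opposite strand, 18 rose (6.12%) and 18 fell, with a median of -0.02 (camera adjusted p = 0.95). Among these control genes 43 rose and 48 fell with the replicate block. Genes whose more abundant neighbour lay at their 3-prime side rose in 46 of 423 cases (10.9%) with that neighbour on the opposite strand and in 48 of 395 (12.2%) with it on the same strand; 78 and 76 of them were also tandem genes. Among the tested genes in none of these neighbour sets 5.56% rose. The difference in median between the tandem and control genes was 0.21, 0.20 and 0.34 in the 3 same-numbered pairs.

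NPC1L1 lies downstream of DDX56, which had a mean of 122 CPM and a log2 fold change of -0.37 ± 0.10, against 6.90 ± 0.40 for NPC1L1 itself. FUT5 (4.02 ± 0.28) follows NDUFA11, a subunit of respiratory complex I (89.1 CPM, -0.42 ± 0.10). CACNG1 and CACNG4, calcium channel subunits, differed: CACNG1 rose from 0.573 ± 0.0577 to 8.18 ± 2.54 CPM (SD, n = 3 each), a log2 fold change of 3.83 ± 0.28 (SE, edgeR adjusted p = 0.000156), and its neighbour CACNG4 stood at 499 CPM and 0.27 ± 0.12 (edgeR adjusted p = 0.17). CD101 rose by 2.27 ± 0.17 (edgeR adjusted p = 0.000164) beside PTGFRN, at 95 CPM and 0.04 ± 0.10 (edgeR adjusted p = 0.83). Among the tandem genes that fell was QRICH2 (-1.36 ± 0.16, edgeR adjusted p = 0.00101), downstream of PRPSAP1. The PDZD3, ISG20 and ERBB3 genes described above were also downstream tandem genes, of NLRX1, AEN and RPS26.

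Of the 79 genes that rose by at least 8-fold, 34 were downstream tandem genes and 2 were control genes. Tandem genes made up 14.5% of the genes that rose, 2.79% of those that fell and 3.54% of those that did not change. With any expressed upstream neighbour, whatever its abundance, the median was 0.03 and the set did not pass (camera adjusted p = 0.474). Of these 3294 genes 9.14% rose, against 4.66% of 2725 genes with such a neighbour on the opposite strand. How the deposited counts treated strand and overlapping genes is not given in the sources used here, so reads from overlapping neighbours cannot be excluded from single values.

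**Figure D4:**
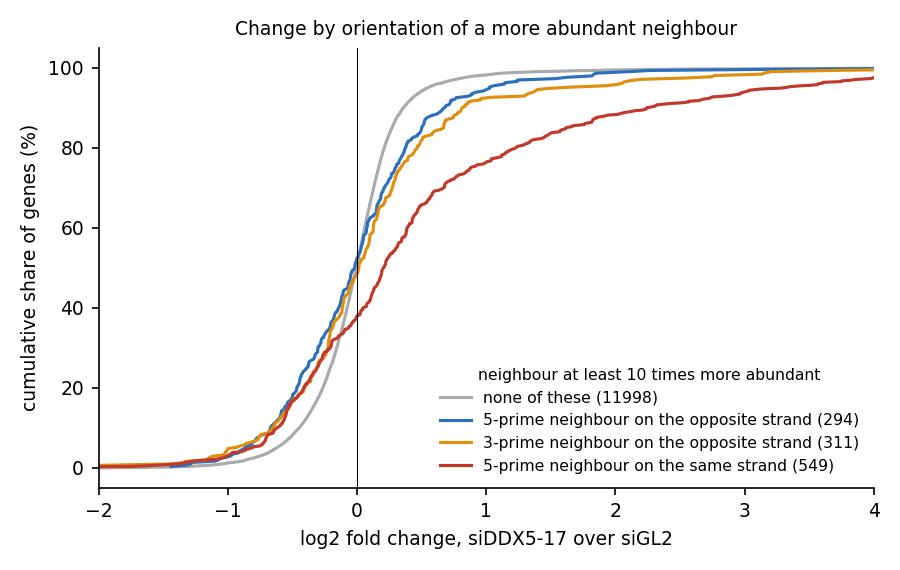
Cumulative share of genes (y axis, %) at or below each log2 fold change of siDDX5-17 over siGL2 (x axis, drawn from -2 to 4), by the orientation of a neighbour at least 10 times more abundant. The curve of the 549 genes with such a 5-prime neighbour on the same strand lies to the right of the others in its upper part. Its median is 0.21, against -0.02 for the 294 with a 5-prime neighbour on the opposite strand. In the lower part the curves cross: its first quartile is -0.31, against -0.21 for tested genes in no neighbour set.

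The authors' deposited table compares the same 6 libraries, so it is no independent evidence. An adjusted p under 0.05 was given to 2896 genes in the authors' deposited table, 1344 higher and 1552 lower in siDDX5-17 cells. Of these, 1920 were also called here, with the same sign in 100% of them. A further 909 were called only in the authors' deposited table, 67 were not tested here, and 102 were called here only. The authors' deposited table gives DDX5 a log2 fold change of -1.52 ± 0.17 (SE), DDX17 -1.25 ± 0.17, CDKN1A 1.53 ± 0.16 and NPC1L1 4.22 ± 0.22. Over the genes called in both, the median absolute log2 fold change was 0.626 here and 0.565 in the authors' deposited table.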

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

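The GC correction, its combination with the replicate block and the neighbour definition restricted to counted genes were chosen after the result was seen; the other alternatives were planned. DDX5 and DDX17 fell past the threshold under all alternatives run, with leave-one-out values from -1.96 to -1.66 for DDX5 and from -1.60 to -1.39 for DDX17. Against 2022 changed genes (841 rose, 1181 fell), the replicate block gave 4878 (2216, 2662), the GC correction 3077 (1526 rose), both together 7461 (3933, 3528) and the test against a 1.5-fold change 251 (168, 83). Leaving out 1 library gave 972 to 2251 genes, 399 to 873 that rose and 573 to 1378 that fell. The highest came without siDDX5-17 replicate 3 (2251, of which 1744 are among the 2022), despite fewer samples. The lowest came without siGL2 replicate 1 (972, of which 944 are among the 2022), and 1112 came without siGL2 replicate 2; fewer samples leave less power, and why these libraries weighed most was not tested. RLE (1983), upper-quartile factors (2005), no filter (2066), the CPM filter (1818), DESeq2 (2552) and limma-voom (2004) stayed within 1.5 times.

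Camera called 7 lists, 4 to 8 without 1 library (4 without siDDX5-17 replicate 3), 0 with an estimated correlation and 3 by fry. The interferon list, which had no direction past any threshold, changed sign in camera with RLE (0.96), upper-quartile factors (0.88), the CPM filter (0.99), the replicate block (0.95), the GC correction (0.92) and the block with GC correction (0.76), and in 3 leave-one-out fits (0.57 to 0.97 over all 6; values are adjusted p). The tandem set kept its direction, with medians of 0.15 to 0.30 without 1 library and 0.33 with no filter. Its median was 0.12 with a neighbour 3 times more abundant (17.3% rose, against 5.04% of the control genes). With neighbours among counted genes only its median was 0.12 (18.1% rose, against 6.37% of the control genes). The tandem set did not pass in camera with an estimated correlation (median 0.21, adjusted p = 0.416). With any expressed neighbour it did not pass either (median 0.03, camera adjusted p = 0.474), and 9.14% rose, against 4.66% of the control genes. The opposite-strand control set, never past the threshold, changed sign in camera with RLE (median -0.01), upper-quartile factors (0.02), the CPM filter (-0.01), the GC correction (-0.01), the block with GC correction (0.00), a neighbour 3 times more abundant (-0.04) and any neighbour (-0.02), and ranged from -0.08 to 0.02 without 1 library. The replicate block ended no call among the named genes and lists and changed no call besides those given with the results above. Among the named genes, calls near the threshold also ended for BDNF with RLE (0.0532), upper-quartile factors (0.0606), no filter (0.06), DESeq2 (0.0885) and limma-voom (0.0519), for RSAD2 and NOVA2 with limma-voom (0.0512 and 0.0509), for HERC5, EGLN3 and CPSF4 with upper-quartile factors (0.0653, 0.0658 and 0.0567), for EGLN3 with the CPM filter (0.0503), for COX5B without a filter (0.0567) and for PHGDH with RLE, upper-quartile factors, the CPM filter, the GC correction and limma-voom (0.0509 to 0.0566). RPS9 passed with DESeq2 (0.0418) and the GC correction (0.0245), RPS19 with the GC correction (0.0369), and the mitosis list without a filter (0.027). Depth limits the size of folds for genes nearly absent from siGL2, such as SIGLEC1 and NPC1L1, with 3 and 13 counts over its 3 libraries. The cause of the other differences was not tested.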

Other observations

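Tests of the shares of risen tandem genes, of the other neighbour orientations, of the mitosis comparison and of the GC trend, whose correction was added later, were chosen after the result was seen; the other tests were set before it.

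A larger share of abundance-matched downstream tandem genes rose than of control genes, by 14.6 percentage points (bootstrap 95% interval 9.52 to 19.7). The control genes had an upstream neighbour on the opposite strand. Each of the 294 control genes was paired with the tandem gene nearest in mean CPM over all 6 libraries. The remaining tandem genes of the 549 were left out. The paired tandem genes had a median mean CPM of 2.07, against 1.66 for all tandem genes. Bootstrap intervals here and below resample genes with their calls and fold changes held fixed. They hold no spread between libraries and treat genes as independent. Camera with an estimated correlation gave the tandem set an adjusted p = 0.42. For the paired genes, the bound of 9.52 points argues against low mean abundance as the whole cause. Abundance in siGL2 cells alone was not matched, so low abundance there stays open. Genes facing a more abundant gene on the opposite strand at their 3-prime side exceeded the control genes by 0.952 points (-3.06 to 4.90) when the 311 genes in neither the tandem nor the control set were taken, which argues against counting without strand as the whole cause; all 423 such genes, 78 of them also tandem, exceeded the control genes by 4.75 points (0.688 to 8.74). A higher level of polyadenylated RNA from the upstream neighbour is argued against too. The neighbours of the risen genes lay lower than those of the other tandem genes (difference -0.08, -0.16 to 0.00). This interval leaves a small fall of the neighbour, down to -0.16, open. Transcription itself was not measured, so higher transcription of the neighbour cannot be judged from these counts. In medians the matched difference was 0.16 (0.07 to 0.26), so neither a shift of 0.20 from run-on nor low abundance (bound 0.07) could be excluded, and the 311 genes facing an opposite-strand neighbour (0.03, -0.06 to 0.13) left strand open on that measure. A candidate explanation for part of the risen share is transcription that runs on past the end of the upstream gene. Genes with a more abundant same-strand gene at their 3-prime side also rose in 12.2% of 395 cases (76 were also tandem). This share lay 6.03 points above that of the control genes (1.88 to 10.3). The 291 of them in no other set rose in 9.62%. That was 3.5 points above the control genes (-0.933 to 7.95) and 12.6 below the tandem genes (7.73 to 17.2). Their median exceeded that of the control genes by 0.09 (0.01 to 0.19). Run-on from the 3-prime gene would not raise them. The 291 can still have a same-strand upstream neighbour that is less than 10 times more abundant. Whether run-on made this shift therefore cannot be told, and reads between genes were not analysed here.

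Changed genes of both directions were richer in GC: median transcript GC was 54.4% in genes that rose and 52.6% in genes that fell, against 47.8% in the other tested genes, a gap of 5.47 points for changed genes together. Matching on abundance left a gap of 5.17 points (4.29 to 6.0) and leaving out the tandem genes one of 5.23 points, which argues against both as the whole cause. With the replicate block the gap was 4.2 points, and 2.82 points after each library's smooth GC trend was also removed, between the bounds set for and against a GC trend between libraries, so that such a trend and an effect of the silencing on GC-rich transcripts cannot be told apart for these genes.

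The median log2 fold change of DNA replication and G1/S genes lay below that of mitosis and G2/M genes. The difference was -0.23 (-0.33 to -0.16 over resampled genes, which holds no spread between libraries). The mitosis list did not pass in the fit of all 6 libraries (camera adjusted p = 0.078). It did with the replicate block (0.021), without a filter (0.027) and in several fits without 1 library. The 3 same-numbered pairs gave -0.32, -0.20 and -0.09 (mean -0.20, SD 0.12), too spread to exclude a lower share of cycling cells, which therefore stays open beside an effect of the helicases on replication genes. A GC trend between libraries is argued against as the whole cause: after its removal, with the replicate block, the replication median was -0.35 and 35 genes fell (camera adjusted p = 4.2e-10), while the mitosis median was -0.11 and 14 genes fell (camera adjusted p = 0.021). In that fit 3528 of all 13152 tested genes fell. With an estimated correlation both lists gave an adjusted p = 0.72, and 0.67 (replication) and 0.77 (mitosis) with the replicate block, so their difference from other genes rests on the preset correlation.

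The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2022 changed genes and was the 1 split with as many. The highest of the other 9 gave 0 in edgeR (6 to 920 genes at an unadjusted p under 0.05). Each of the other 9 mixes both siRNAs within its groups, so the silencing effect adds to the spread within them. Their low counts therefore do not show what groups without a silencing effect would give. Only 3 of these others part all 3 same-numbered pairs as the real split does, and they gave 6 to 91 genes at an unadjusted p under 0.05.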
